A study of Mus musculus with 28 samples.

How the data were processed

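Binding events of the Forkhead factors FoxA1, FoxC1, FoxL2 and FoxP3 were measured by ChIP-exo in mouse ES cells with Dox-repressible, tagged transgenes at Rosa26, per the labels' protocols. Dox was washed out and the cells were grown in differentiation medium for the stated hours before crosslinking, per the same protocols. Groups, time points and antibodies were read from the sample titles and characteristics before the data were examined. The labels gave 21 libraries in 15 groups for what is reported. Some items of this series are not reported here, and the comparisons were recomputed without them after the first results were seen. The second library of the empty control names the anti-FoxA1 antibody in its title and the anti-FLAG antibody in its characteristics, and the empty control has no list used here.

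Reads were mapped with BWA 0.7.17-r1188 to mm10 and handled with Picard and SAMtools, per the submitters' processing notes. The events were called with ChExMix, per the file headers. The caller's version, controls, thresholds and blacklist, and how the libraries of a factor were combined into 1 list, are not given in the sources used here. The deposited value of each event is a score, a whole number between 43 and 1000 per the file headers' event lists, and its scale is not given. Scores reach a ceiling at 1000, so the strongest events of long lists tie. All 14 lists held events, all 1 bp wide. The files hold no reads or totals, so depth is unknown and precision is given as Wilson 95% intervals on shares of events and, for 1 ratio of counts, as an exact binomial 95% interval.

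Positions were used as deposited, on mm10. Gene positions came from a table of the GRCm38.p6 annotation, the same build, with 21887 protein-coding genes (49943 genes of all types) on chromosomes 1 to 19, X and Y. It gives no strand, so both ends of each gene were used in place of the transcription start site, a departure from the plan made because of the table. No genome sequence was in the reference used, so the planned motif counts were not run.

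Overlap was the percent of a list's events with an event of another list within 100 bp. It was set against 1000 random placements of the first list on its own chromosomes, with a one-sided permutation p whose smallest value is 0.001. The same measure was used between Forkhead factors, between the antibodies of the FoxA1 time courses, and from each time point to the next. Benjamini-Hochberg adjustment was made within each of these families of comparisons. Sites were built from the 4 combined lists by joining events within 100 bp. Gene ends were tested as the percent of events within 1 kb of a protein-coding gene end, with a two-sided permutation p from 1000 placements, in the 11 lists with at least 20 events on these chromosomes.

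For 13 gene lists, the number of genes with an event within 50 kb of either end was compared with 10000 random lists of the same size matched on decile of gene density within 500 kb. A list was called above the 99th or below the 1st percentile, and no p was computed, since genes are not replicates. Random lists with the same count as the observed one were ranked at their midpoint. The lists were fixed before the data were examined: pluripotency, endoderm regulators, liver, forebrain, proneural and Notch targets, mesoderm, granulosa cell, regulatory T cell, trophectoderm, signalling feedback and housekeeping genes, the Forkhead family and the Hox genes. All 210 symbols of the 11 lists typed in full matched the gene table.

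Named genes followed a rule fixed before the data were examined. For each Forkhead factor at 24 h and the last time point of each course they were up to 4 members with the most events (ties by the nearest event) of each called list and of the list of the factor's best known tissue, the 10 genes with the most events within 50 kb (genes with the same set of events counted as 1), the genes nearest the 5 highest scores, and the factor's own gene and Rosa26. Where more than 10 events tied at the ceiling no highest scores were named, and where up to 10 tied all were.

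Results were recomputed with alternatives, 1 choice at a time. Every kind of result was recomputed with the higher-scoring events alone, overlaps and sites also with other distances, and gene ends and gene lists with other windows. Autosomes alone were used for list lengths, overlaps, retention and sites, and events near those of a 0 h list were left out for these and for gene ends. Lists of equal size were used for the factor overlaps and the gene lists, local random placement for the factor overlaps, and other random lists for the gene lists. Alternatives that leave out runs of at least 5 events with gaps of at most 500 bp, measure from the gene interval, count events in place of genes, draw event lists to 1112 for the gene lists, or match random lists also on gene length were added after the data were seen. Leaving out a replicate was not possible, since the combined lists cannot be taken apart. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

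The code was tested on simulated data. A list of the length of the FoxP3 list was placed at random, with events planted inside the 50 kb window of chosen genes. By construction 200 of 200 planted genes had an event, and 10 of 10 planted lists were called, while 3 of 200 random lists were. Planted overlaps of 5% and 50% were recovered as 5.20% and 50.1% for FoxP3 in FoxA1, and 1 of 100 independent pairs of lists gave a permutation p under 0.05. These pairs were placed evenly at random, so they do not test lists whose events gather in the same regions.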

Results

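ChIP-exo, in which lambda exonuclease trims immunoprecipitated DNA back towards the crosslinked protein, was used to map the sites of 4 Forkhead transcription factors in mouse embryonic stem (ES) cells. Each line derived from MC1 ES cells (129S6/SvEvTac) and carried a FLAG-tagged factor at the Rosa26 locus that was silent in doxycycline (Dox), so that washing Dox out induced it. The 21 libraries used here fell into 3 kinds of groups. FoxA1 (3 libraries) and FoxC1, FoxL2 and FoxP3 (2 libraries each) were profiled 24 h after Dox removal, and each factor had 1 list of binding events. These lists name only the factor and were taken to combine its libraries, which for FoxA1 were 2 with anti-FLAG and 1 with anti-FoxA1. They are called combined lists below. Time courses at 0, 6, 12, 24 and 48 h had 1 library and 1 list per time point and covered FoxA1 with anti-FLAG and with an anti-FoxA1 antibody. The 2 libraries of an empty control line at 0 h had no list used here. The 14 lists held 162571 events, each 1 bp wide, on the mm10 genome, with a score from the event caller between 43 and 1000 whose scale is not given in the sources used here. The files hold events and no reads, so the sequencing depth behind each list is unknown. No list has a replicate with the same antibodies beside it, and no test across replicates was possible. Intervals on shares of events are Wilson 95% intervals and cover counting error only.

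The number of events differed widely between the factors. FoxA1, a pioneer factor of endoderm and liver, had 32948 events at 24 h. FoxL2, a factor of ovarian granulosa cells, had 7244, FoxP3, the lineage factor of regulatory T cells, had 4385, and FoxC1, a factor of mesoderm and mesenchyme, had 1112. With anti-FoxA1, FoxA1 events went from 15 at 0 h to 86 at 6 h, 8345 at 12 h, 35134 at 24 h and 41726 at 48 h. With anti-FLAG the same factor gave 20, 17, 1656, 15984 and 13899 events at these times. List size depends on depth and on the antibody as well as on binding, and these numbers were not tested against each other. Of the 20 events in the anti-FLAG list at 0 h, 18 lay on the mitochondrial genome, which left 2 on the chromosomes of the nucleus.

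**Figure D1:**
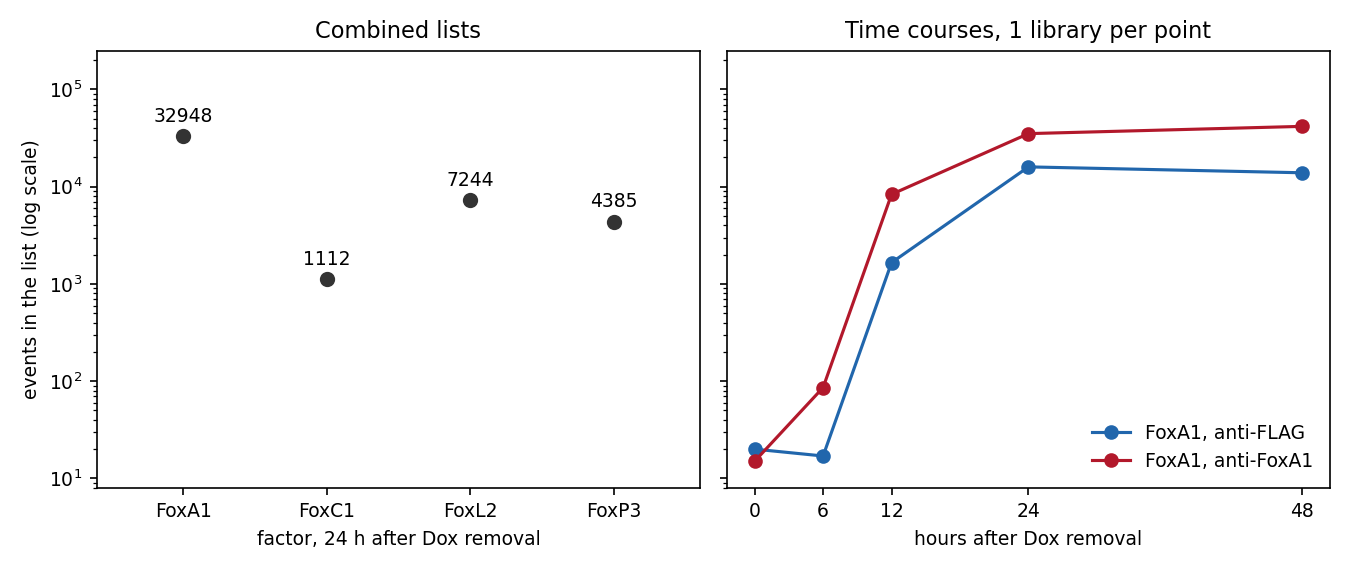
Number of events per list on a log axis, for the combined lists of the 4 Forkhead factors (left) and along the 2 time courses of FoxA1 against hours after Dox removal (right); each point is 1 list. FoxA1 had 32948 events and FoxC1 1112, and both FoxA1 time courses passed 1000 events at 12 h.

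The factors' own genes, at their native loci and not the induced transgene, carried no events of the factor they encode. Foxa1, Foxc1, Foxl2 and Foxp3 each had 0 events within the gene and 1 kb to either side in the lists of the factor they encode. At the Rosa26 locus, which holds the transgene (Gt(ROSA)26Sor, chromosome 6, 113067428–113077244), the combined FoxA1 list had 1 event, at position 113076607 with a score of 74, and all other lists had none. In the combined lists the nearest FoxA1 event to Foxa1 lay 25098 bp away and the nearest FoxC1 event to Foxc1 1033480 bp away, while the anti-FoxA1 list at 48 h had an event 3405 bp from Foxa1.

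How far the Forkhead factors share sites in the same cells was measured as the share of a list's events with an event of another list within 100 bp. FoxC1 events coincided with FoxA1 events in 53.3% (50.4–56.2), with FoxL2 events in 41.2% (38.3–44.1) and with FoxP3 events in 26.7% (24.2–29.4). FoxP3 shared 42.6% (41.1–44.0) with FoxA1, 15.0% (13.98–16.1) with FoxL2 and 6.84% (6.13–7.63) with FoxC1. FoxL2 shared less with FoxA1, 18.5% (17.6–19.4), and 9.14% (8.50–9.82) with FoxP3 and 6.35% (5.81–6.94) with FoxC1. FoxA1, the longest list, coincided with FoxP3 in 5.85% (5.60–6.11), with FoxL2 in 4.19% (3.98–4.41) and with FoxC1 in 1.94% (1.79–2.09).

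Random placement of the first list's events on their own chromosomes gave means between 0.00904% and 0.262%, and all 12 comparisons gave a one-sided permutation p of 0.001, before and after Benjamini-Hochberg adjustment, the smallest that 1000 placements can give. Relative to these means the order of partners turned, and the share in FoxA1 was the lowest for each other factor. FoxC1 was 203 times its random mean in FoxA1, 295.5 times in FoxL2 and 518 times in FoxP3. For FoxP3 it was 163 times in FoxA1, 231.5 in FoxL2 and 507 in FoxC1. For FoxL2 it was 71.8 times in FoxA1, 228 in FoxP3 and 277 in FoxC1. For each factor these ratios fell as the list searched grew longer, since a longer list raises the random mean. Neither the shares nor these ratios rank the partners apart from list length. With every list drawn at random to 1112 events, the 9 shares measured in FoxA1, FoxL2 or FoxP3 fell to between 0.0355 and 0.26 of their value, and the 3 measured in FoxC1, which loses no events, stayed within 1.02 times. Such a draw lowers a share by construction, by about the part of the other list that is removed, and does not rank the partners. A shared base in place of 100 bp left 0.0420 to 0.321 of each share. The anti-FLAG time-course list at 24 h in place of the combined FoxA1 list moved 2 of 6 shares by more than 1.5 times, among them FoxP3 in FoxA1, which was 20.0% (18.8–21.2).

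**Figure D2:**
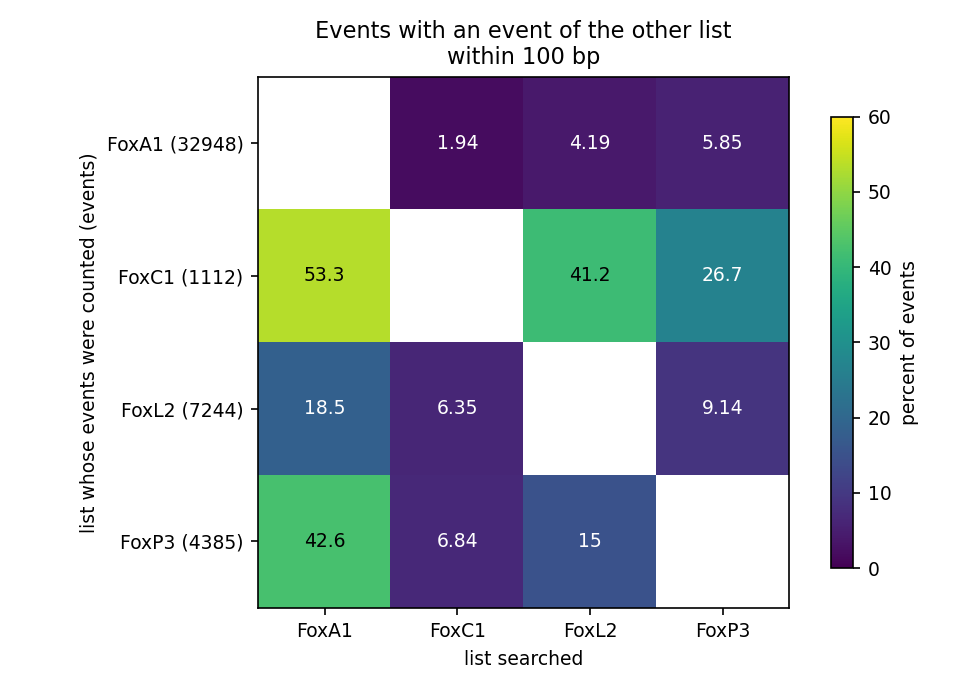
Percent of the events of each Forkhead factor's 24 h list (rows, with the number of events) that have an event of another factor's list (columns) within 100 bp. The column of FoxA1, the longest list, is the highest for every other factor, with 53.3% of FoxC1 events and 42.6% of FoxP3 events. These percents depend on the length of the list searched. Relative to random placement, the share in FoxA1 was the lowest for every other factor. That ratio also falls with the length of the list searched, so neither measure ranks the partners.

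Joined at 100 bp, the 4 lists made 40974 sites, of which 37452 were in 1 list, 2865 in 2, 529 in 3 and 128 in all 4. FoxA1 alone accounted for 29561 sites, FoxL2 alone for 5429, FoxP3 for 2163 and FoxC1 for 299. Of each factor's own sites, 90.6% of those of FoxA1 and 75.3% of those of FoxL2 were in no other list, compared with 49.8% for FoxP3 and 26.99% for FoxC1. Absence from another list does not show absence of binding, since FoxA1 lists at 24 h met each other only in part. Of the combined FoxA1 events, 54.8% lay in the anti-FoxA1 list at 24 h and 33.0% in the anti-FLAG list. The most frequent pair was FoxA1 with FoxP3 (1395 sites), ahead of FoxA1 with FoxL2 (834), FoxL2 with FoxP3 (249) and FoxA1 with FoxC1 (230). Which of FoxP3 and FoxL2 came first depended on the FoxA1 list. Counted as events, 876 of FoxP3 and 910 of FoxL2 lay at anti-FLAG events of 24 h. At anti-FoxA1 events of 24 h lay 1430 of FoxP3 and 1226 of FoxL2. Sites in all 4 lists included 2 near Foxd3, a Forkhead factor of ES cells and neural crest, and single sites near Otx2, near Prdm14, in Foxp1 and in Zmynd8, genes singled out after their values were seen. Another 2 flanked Nanog, the homeobox factor of naive pluripotency, which was drawn for the same reason.

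Shared sites had the higher scores in every list, a difference that was not tested. The median FoxA1 event without another factor within 100 bp sat at score percentile 47.7 of its list, and the median event with all 3 others sat at 90.6. For FoxL2 these percentiles were 46.6 and 82.0, for FoxP3 39.7 and 79.95, and for FoxC1 28.01 and 67.2. The number of sites in all 4 lists depends on the distance allowed and was 83 at 50 bp and 2 at a shared base. Sites within 1 kb of the end of a protein-coding gene made up 5.11% (4.89–5.34) of sites in 1 list, 3.84% (3.20–4.61) of sites in 2, 4.35% (2.91–6.44) of sites in 3 and 5.47% (2.67–10.9) of sites in all 4, which was not tested.

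Around Nanog (gene ID 71950, chromosome 6, 122707489–122714633), all 4 factors had events within 100 bp of each other at a pair of places. The nearer one lay at 122690370, 17119 bp from the gene, and the other at 122762710, inside Slc2a3, which encodes a glucose transporter. At the nearer place the scores were 557 for FoxC1, 213 for FoxL2, 162 for FoxP3 and 148 for FoxA1, and at the other they were 1000 for FoxA1, 611 for FoxP3, 202 for FoxC1 and 58 for FoxL2. Both FoxA1 time-course lists at 24 h also had events at both places. Within 50 kb of Nanog, FoxA1 and FoxP3 had 6 events each, FoxC1 4 and FoxL2 2.

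**Figure D3:**
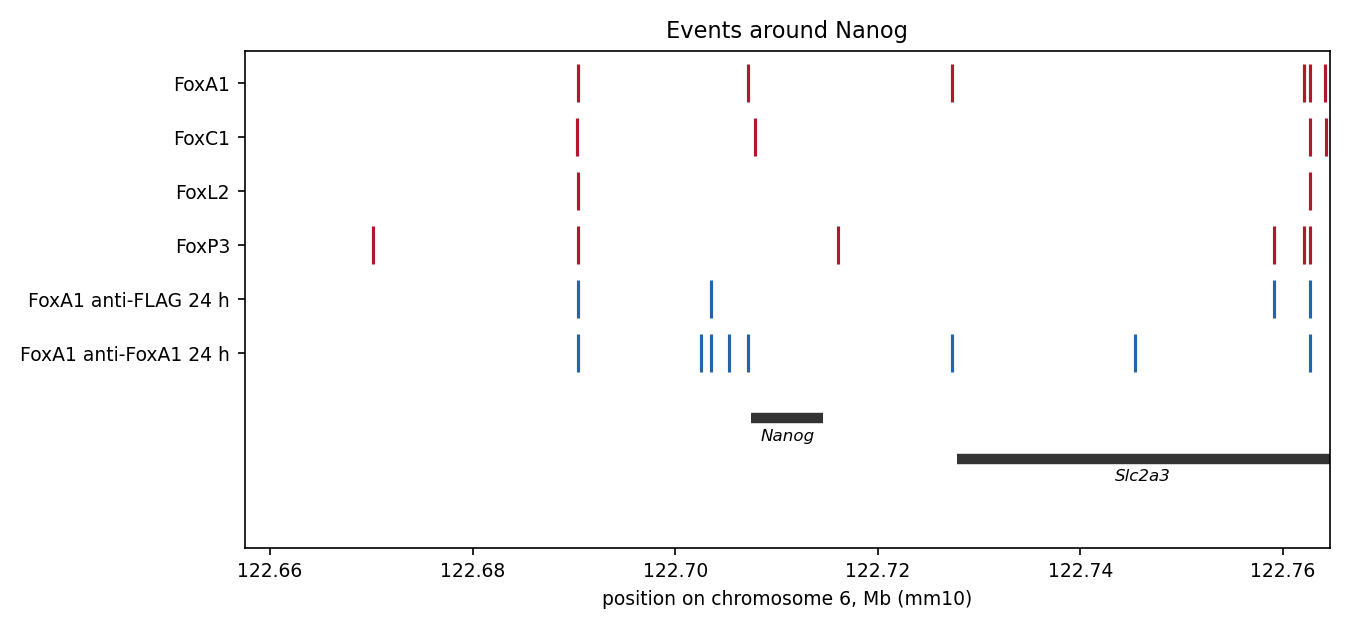
Events (vertical ticks) of 6 lists at 24 h by position in Mb on chromosome 6 (mm10), in a window reaching 50 kb to either side of Nanog; bars below are the protein-coding genes. All 4 combined Forkhead lists and both FoxA1 time-course lists have events around 122690370 and 122762710.

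The gene lists fixed in advance were compared with the events by counting the genes with an event within 50 kb of either gene end, against 10000 random lists of the same size matched on local gene density. Genes of the pluripotency network stood out for all 4 Forkhead factors against these random lists. The random lists were not matched on expression or open chromatin in ES cells, and no empty control list was used. Whether the excess is particular to Forkhead binding was therefore not tested. FoxP3 had events near 15 of the 20 pluripotency genes where random lists averaged 4.02, FoxC1 near 9 (random mean 1.32), FoxL2 near 14 (6.07) and FoxA1 near 19 (14.1). No random list reached the count of FoxP3 or of FoxC1, 1 of 10000 reached that of FoxL2, and the FoxA1 count was at percentile 99.6. Nanog, Klf2, Tbx3, Prdm14, Dppa3, Dppa5a and Tdgf1, 7 of the 20 genes, had events of all 4 factors, against a random mean of 0.575, and none of the 10000 random lists had as many. This joint count follows in part from the 4 single counts and is not separate support. It counts genes and not shared places. Of the 128 sites in all 4 lists, 3 lay within 50 kb of a pluripotency gene end, among them the pair around Nanog (2.34%, 0.800–6.66, against 0.41% of all sites). The share was 0.374% for sites in 1 list, 0.803% in 2, 0.378% in 3 and 2.01% for FoxC1 alone. It thus did not rise steadily with the number of lists.

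The pluripotency genes with the most events were in part the same for several factors, with Nanog first for FoxP3 and FoxC1. For FoxA1 the most events were near Esrrb, an orphan nuclear receptor of naive ES cells (21 events), Klf5 and Prdm14 (12 each), and Klf4, Sall4, Dppa5a and Tdgf1 (8 each). For FoxP3 they were near Nanog (6 events), Dppa5a (5), Klf5 (5), and Sall4, Tbx3 and Prdm14 (3 each), and the nearest to Dppa5a lay 779 bp away. For FoxL2 they were near Klf5 (6 events), and Klf4, Tbx3, Klf2, Pou5f1, Nanog and Prdm14 had 2 each. For FoxC1 they were near Nanog (4 events) and Prdm14 (2), ahead of 7 genes with 1 each (Lin28a, Tbx3, Klf2, Esrrb, Dppa3, Dppa5a and Tdgf1), and a FoxC1 event lay inside Nanog, 392 bp from its end. Calls were made above the 99th or below the 1st percentile and describe these lists, since genes are not replicates. The FoxA1 call was lost with a 100 kb window (percentile 93.7) and the FoxL2 call with a 20 kb window (percentile 98.0).

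Genes of feedback in the Nodal, BMP, WNT and FGF pathways were called for FoxA1 and FoxP3. Here and below, up to 4 members of a list are named, and where more had the same number of events, those with the nearest event. FoxA1 had events near all 17 (random mean 12.4), most near Dusp6 (13 events), a phosphatase that restrains ERK signalling, then Smad7 (9), Id3 (8) and Lefty1 (7). FoxP3 had events near 8 (random mean 3.67), most near Spry2 (6), Spry4 (4), Fzd7 (3) and Id1 (3). The strongest FoxP3 event near Fzd7 had a score of 1000. The Forkhead gene family was called for FoxA1, near 40 of 44 genes (random mean 31.7), with 12 events near Foxd3, 11 near Foxn3, 8 near Foxb1 and 6 near Foxp4. All 3 of these calls were lost in at least 1 setting: for feedback genes with a 100 kb window, at percentile 97.3 for FoxA1 and 94.3 for FoxP3, and for the Forkhead family with a 20 kb window (percentile 92.2).

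Hox genes, which pattern the body axis, were near FoxA1 events in 38 of 39 cases (random mean 29.2), and fell below chance for FoxP3, with 2 of 39 (7.84). The FoxA1 event nearest Hoxc4 lay 85 bp from it, and FoxP3 reached Hoxb13 (2 events) and Hoxc13 (1). Hox genes lie in clusters and share events, so their percentiles overstate how unusual these counts are. By the number of events the Hox genes had fewer FoxA1 events than random lists, 81 against 96.1, at percentile 17.9, and with lists drawn to 1112 events FoxA1 (percentile 28.1) also fell below the middle of the random lists. The time-course lists of FoxA1 at 24 h were not called, with 30 of 39 Hox genes for anti-FoxA1 (random mean 29.7, percentile 52.7) and 15 of 39 for anti-FLAG (20.9, percentile 3.09). By the number of events both lay below the 1st percentile. Anti-FoxA1 had 64 events against 108.8 (percentile 0.46) and anti-FLAG 20 against 46.5 (percentile 0.11). For FoxP3, 6 settings ended the call, with the 100 kb window at percentile 40.8.

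Genes of the tissue where each Forkhead factor is best known were not called in the combined lists. FoxA1 had events near 17 of 20 endoderm regulators (random mean 14.2, percentile 91.4), with 7 events near Cer1, a secreted Nodal antagonist, 5 near Gata6 and 4 near Prox1. It had events near 16 of 20 liver genes (14.5, percentile 75.9), among them Tat, tyrosine aminotransferase (6 events), the fibrinogen genes Fgb and Fga (5 each, the same cluster) and Trf (5). FoxL2 had events near 4 of 20 granulosa cell genes (6.15, percentile 15.4), namely Amhr2 (4 events), Bmp2 (2), Star (1) and Esr2 (1). FoxP3 had events near 4 of 20 regulatory T cell genes (4.26, percentile 46.2), namely Ikzf4 (4 events), Ptpn22 (2), Nt5e (1) and Il2ra (1). FoxC1 had an event near 1 of 20 mesoderm, mesenchyme and vascular genes (1.40, percentile 41.0), Hey1, at 26866 bp.

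The endoderm list was called for FoxA1 with a 20 kb window (percentile 99.5). FoxA1 windows took in 73.4% of all protein-coding genes, which leaves little room above chance. Over 13 gene lists and 11 event lists, 143 combinations in all, 20 were called higher and 1 lower, where chance gives 1.43 in each direction. The combinations are not independent, since the FoxA1 lists share many events. The pluripotency list alone gave 10 of the higher calls. Liver genes ranged from percentile 1.73 to 96.6 over the 11 event lists, forebrain genes from 14.6 to 97.2, mesoderm genes from 33.7 to 93.4 and granulosa cell genes from 10.5 to 98.7. Regulatory T cell genes ranged from 8.62 to 92.6, trophectoderm genes from 36.2 to 95.7, housekeeping genes from 9.30 to 94.8 and proneural and Notch pathway genes from 5.52 to 85.1, and none of these 8 lists was called.

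**Figure D4:**
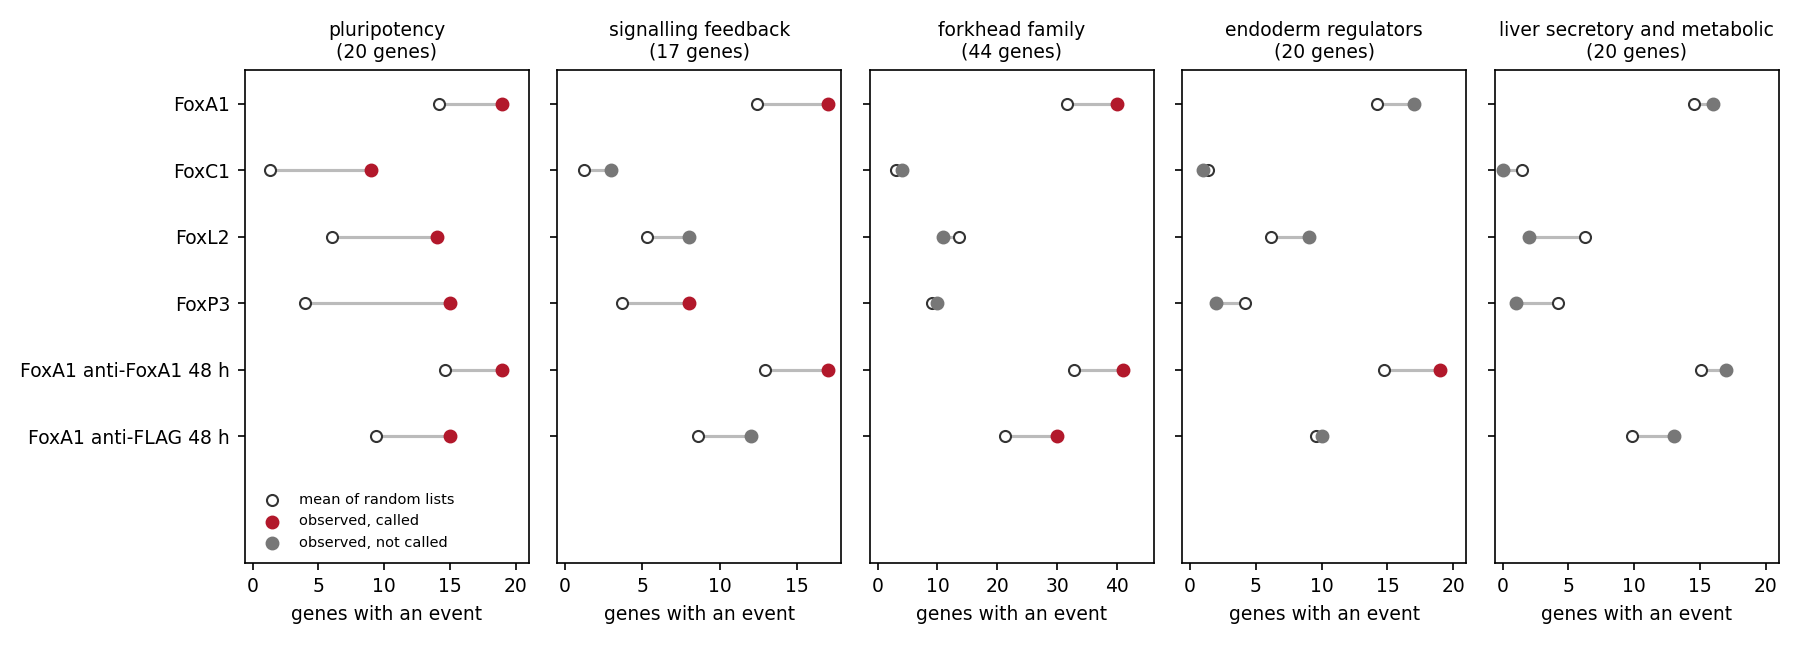
Number of genes of 5 fixed lists with an event within 50 kb of a gene end, for 6 event lists (rows); open circles are means of 10000 density-matched random lists and filled circles the observed counts, red where called. Pluripotency genes are called in all rows, and endoderm regulators only with anti-FoxA1 at 48 h, near 19 of 20.

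Whether anti-FLAG and anti-FoxA1 found the same FoxA1 sites was compared at each time. Nearly all anti-FLAG events were in the anti-FoxA1 list: 90.3% (88.8–91.7) at 12 h, 86.0% (85.4–86.5) at 24 h and 90.2% (89.7–90.7) at 48 h. The longer anti-FoxA1 lists had 18.7% (17.9–19.6), 40.5% (40.03–41.1) and 31.0% (30.6–31.5) of their events in the anti-FLAG lists. At 6 h, 4 of 17 anti-FLAG events and 3 of 86 anti-FoxA1 events were shared, and at 0 h none were. The combined FoxA1 list had 54.8% (54.3–55.4) of its events in the anti-FoxA1 list at 24 h and 33.0% (32.5–33.5) in the anti-FLAG list. The permutation p was 0.001 (0.00125 after Benjamini-Hochberg adjustment over 10 comparisons) from 6 h on, the smallest possible, and 1 at 0 h. A shared base in place of 100 bp left at most 0.116 of each share, and none of the events at 6 h.

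FoxA1 sites found early were mostly found again. With anti-FoxA1, 85 of 86 events at 6 h were present at 12 h, 89.2% (88.5–89.9) of 12 h events at 24 h, and 72.0% (71.6–72.5) of 24 h events at 48 h. With anti-FLAG, 95.1% (94.0–96.1) of 12 h events were present at 24 h and 61.3% (60.5–62.0) of 24 h events at 48 h, while 4 of 17 events at 6 h were present at 12 h. Of the 15 anti-FoxA1 events at 0 h, 6 were present at 6 h, and none of the anti-FLAG events at 0 h was. The permutation p was 0.001 for 7 of the 8 steps (0.00114 after Benjamini-Hochberg adjustment), the smallest possible, and 1 for the anti-FLAG step from 0 h. No test between time points was made, and a shared base in place of 100 bp left at most 0.118 of each share.

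Sites found earlier had higher scores at 48 h. For anti-FoxA1, events at 48 h that were first called at 12 h (7434) had a median at score percentile 82.7, those first called at 24 h sat at 60.2 and those called only at 48 h at 27.6. The 102 first called at 6 h sat at 98.1 and the 16 first called at 0 h at 97.1. For anti-FLAG the values for 12, 24 and 48 h were 87.3, 57.3 and 24.2. The share of anti-FoxA1 sites within 1 kb of a gene end was 4.31% (3.87–4.79) for those from 12 h and 6.28% (5.91–6.66) for those only at 48 h. With anti-FLAG it was 3.16% (2.40–4.14) from 12 h, 3.54% (3.16–3.96) from 24 h and 3.28% (2.78–3.88) only at 48 h. Whether late sites were bound later or only passed the score threshold later cannot be read from these lists, and no test was made.

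Pluripotency genes were called in both FoxA1 time courses at 12, 24 and 48 h. At 6 h the 86 anti-FoxA1 events lay near 0 of the 20 genes (random mean 0.107), and the anti-FLAG list was too short to test. The lists at 6 h are too short to date an onset. Anti-FLAG events lay near 9 of 20 at 12 h (random mean 1.87), 16 at 24 h (9.83) and 15 at 48 h (9.37), and anti-FoxA1 events near 16 at 12 h (6.80) and 19 at both 24 h (14.02) and 48 h (14.6). At 48 h Klf5 had 9 anti-FLAG and 16 anti-FoxA1 events, Prdm14 8 and 21, Esrrb 7 and 20, and Tbx3 5 and 13. The strongest anti-FLAG events near Klf5 and Esrrb had a score of 1000. Feedback genes were called with anti-FoxA1 at 12 h (12 of 17, random mean 6.27) and 48 h (all 17, 12.9), with 13 events near Smad7, 11 near Lefty1, and 10 each near Dusp6 and Lefty2 at 48 h. The Forkhead family was called with anti-FoxA1 at 24 h (40 of 44, 31.6) and 48 h (41, 32.9) and with anti-FLAG at 48 h (30, 21.3). At 48 h Foxp4 had 15 anti-FoxA1 events, Foxp1 13, Foxj1 12 and Foxo3 11, and Foxj1, Foxd3 and Foxn3 had 6 anti-FLAG events each and Foxp4 4.

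Endoderm regulators were called at 48 h with anti-FoxA1, near 19 of 20 genes (random mean 14.7), with 16 events near Gata4 and 6 near Prox1. With anti-FLAG at 48 h the count was 10 of 20 (9.58, percentile 57.5), with 4 events near Gata4, 3 near Prox1 and 2 near Foxa2. Liver genes had events near 17 of 20 with anti-FoxA1 (15.1) and 13 of 20 with anti-FLAG (9.87) and were not called. Fgb, Fga and Apoa1 had 10 anti-FoxA1 events each and Tat 8, and with anti-FLAG Fgb and Fga had 5 and Ahsg and Fgg 3. The endoderm call at percentile 99.1 was lost in 6 of 9 settings, down to percentile 94.3. At 48 h the pluripotency call was lost with a 100 kb window for anti-FoxA1 (percentile 92.1) and for anti-FLAG (percentile 97.9), and liver genes were called for anti-FLAG in that window (percentile 99.3).

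Events near gene ends, used in place of transcription start sites because the annotation used has no strand, were more frequent than by random placement in most lists. Among the combined lists the share was 5.52% (4.32–7.02) for FoxC1, 5.26% (5.03–5.51) for FoxA1, 4.75% (4.16–5.42) for FoxP3 and 3.33% (2.94–3.77) for FoxL2, where random placement gave 3.03 to 3.13%. With anti-FoxA1 the share was 4.32% (3.91–4.78) at 12 h, 4.91% (4.69–5.14) at 24 h and 5.51% (5.29–5.73) at 48 h, and at 6 h 3 of 86 events. With anti-FLAG it was 3.44% (2.67–4.43) at 12 h, 3.39% (3.12–3.68) at 24 h and 3.42% (3.13–3.74) at 48 h. From 42.4% of FoxP3 to 48.5% of FoxA1 events in the combined lists lay inside protein-coding genes, where random placement gave 40.25% and 40.32%.

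The two-sided permutation p for gene ends was 0.001, the smallest possible (0.00183 after Benjamini-Hochberg adjustment over 11 lists), for 6 lists. It was 0.142 for FoxL2, 1 for anti-FoxA1 at 6 h, and 0.448, 0.0270 and 0.0190 for anti-FLAG at 12, 24 and 48 h in the permutation test, or 0.173, 1, 0.492, 0.0371 and 0.0298 after adjustment. Within 500 bp of a gene end, anti-FLAG at 24 and 48 h and FoxC1 no longer passed the threshold, at 1.68%, 1.67% and 2.26%, where random placement gave 1.61 to 1.65%. FoxL2 and anti-FLAG at 12 h passed the threshold within 5 kb, at 16.1% and 17.9%.

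The genes with the most events within 50 kb differed between factors and overlapped in part. For FoxA1 they were Irf2bpl (33 events), Mycn, a MYC family oncogene (30), Nlrp12 (29), Pigl and Jarid2, a Polycomb cofactor (25 each). Pik3cb and the histone gene H3c8 (24 each), H2ac10 (23), and Zmynd8 and H3c7 (22 each) followed. For FoxL2 they were Otx2, a homeobox factor of the primed epiblast and forebrain (12), Mtus1 (11), Mta3 and Pcm1 (8 each), and Tmem231, Mnat1, Mpp5, Bcar1, Cfdp1 and Dse (7 each). For FoxP3 they were Nlrp12 (21), AU018091 (14), Dennd2a, Etnk1 and Mta3 (9 each), Kcng3 (8), and Jarid2, Col18a1, Deptor and Dlgap1 (7 each). For FoxC1 they were Nlrp12 (14), AU018091 and Ninj2 (8 each), Trnau1ap, Otx2, Zmynd8 and Larp1 (5 each), and Nanog, Pik3cb and Pa2g4 (4 each). The events near Nlrp12 (gene ID 378425, chromosome 7, 3218643–3249771) lay in part over the miR-290 microRNA cluster at its edge, which is highly expressed in ES cells.

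At 48 h the anti-FoxA1 list had the most events near Irf2bpl (35), Clmn (33), Itga6 (30), Plpp3 and Zmynd8 (29 each), Pik3cb (27), Mboat2 and Cipc (26 each), and Frmd6 and Rock2 (25 each). The anti-FLAG list had them near Zfp960 and Mboat2 (14 each), Cox10, Tango6 and Hs3st3b1 (12 each), Arid5b, Zfp97, Plpp3 and 1700028P14Rik (11 each), and Larp1 (10). These counts were not tested.

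The highest FoxC1 scores were 1000 in Grb2 (chromosome 11, position 115685680) and in Baz1a (chromosome 12, 54901504), then 920 at 12319 bp from Asgr1, 885 in Ankrd6 and 853 in Foxp1 (chromosome 6, 99439864). The FoxL2 list had 9 events at the highest score of 1000, in or nearest Zwint, Rpl10l, Hecw1, Cdc14b, Fndc7, Fam241a, Synm, Irs2 and AF366264. FoxA1 had 1084 events at this highest score and FoxP3 28, as did 478 anti-FoxA1 and 213 anti-FLAG events at 48 h, so the strongest could not be ranked.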

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

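The tests of the anti-FoxA1 events at 0 h were all chosen only after the result was seen.

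The anti-FLAG FoxA1 list at 0 h had 18 of its 20 events on the mitochondrial genome, which the comparisons with genes do not use, between positions 282 and 12966 with scores from 45 to 219, and 0 of the 13 other lists with events had any there.

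The anti-FoxA1 list at 0 h, before Dox removal, held 15 events, all on autosomes, among them 1 with a score of 280 at 27391 bp from Atf7ip and 1 at 14382 bp from Foxd3, and all 15 had events within 100 bp in the anti-FoxA1 lists at 12 and 24 h. Of these 15 events, 80.0% (54.8–93.0) lay at anti-FLAG events of 24 h, where 40.5% of all anti-FoxA1 events of 24 h did. The matching 24 h events had a median score percentile of 93.6 (lowest 33.8, highest 99.5), and the comparison was not matched on score. The contrast therefore cannot decide for or against binding of the antibody to a protein at places that FLAG-tagged FoxA1 does not reach. A related protein at the same sites would also not be seen by this test. Reads carried over from induced libraries may still account for the 15 events, since the matching 24 h events scored high. Low expression of FoxA1 before Dox removal predicts the same, so carried-over reads and low expression cannot be told apart. The empty control line was not analysed here, and background called with any antibody was not tested.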

How the results depend on the processing

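The gene-interval, event-number, equal-size and gene-length settings for gene lists, and the settings without dense runs of events, were added only after the results were seen. Of the alternatives run, direction and side of the threshold were kept in all 120 for overlap between Forkhead factors, 56 of 58 for the antibodies, 44 of 46 for retention, 56 of 66 for gene ends and 165 of 205 for gene lists. For the Forkhead overlaps this asks only that a share exceed random placement, and shares as low as 0.0355 of the main value counted as kept. Counts stayed within 1.5 times in 53 of 70 for list lengths and 13 of 18 for sites. Where nothing else is said below, the cause was not tested.

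With a shared base in place of 100 bp, overlap was 0 between the antibodies at 6 h in both directions, and 0 for retention of anti-FLAG events from 6 h and of anti-FoxA1 events from 0 h, all from few events.

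Keeping only the higher-scoring events shortens each list by construction: 16474 for FoxA1, 556 for FoxC1, 3622 for FoxL2 and 2192 for FoxP3. It left 10, 8, 828, 7992 and 6949 anti-FLAG events and 7, 43, 4172, 17567 and 20863 anti-FoxA1 events at 0, 6, 12, 24 and 48 h. Sites then numbered 20440, with 18705 in 1 list and 67 in all 4. On autosomes alone the anti-FLAG list at 0 h kept 2 events, and leaving out events near those of a 0 h list empties both FoxA1 lists at 0 h (0 events) by construction. Sites in all 4 lists numbered 83 at 50 bp and 2 at a shared base.

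Near gene ends, the permutation p no longer passed the threshold within 500 bp for FoxC1 (2.26%) and anti-FLAG at 24 h (1.68%) and 48 h (1.67%). With higher scores alone it no longer passed for anti-FLAG at 24 h (3.21%, random 3.09%) and 48 h (3.38%, random 3.09%), where the share at 48 h was close to that of all events (3.42%). It newly passed within 5 kb for FoxL2 (16.1%) and anti-FLAG at 12 h (17.9%), and with genes of all types for FoxL2 (7.54%), anti-FLAG at 12 h (9.06%) and anti-FoxA1 at 6 h (11.6%).

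Gene lists are given by percentile. With a 100 kb window calls were lost for pluripotency in FoxA1 (93.7), anti-FoxA1 48 h (92.1) and anti-FLAG 48 h (97.9) and for endoderm in anti-FoxA1 48 h (98.6), and gained for liver in anti-FLAG 48 h (99.3). With 20 kb they were gained for endoderm in FoxA1 (99.5) and lost for pluripotency in FoxL2 (98.0). Without density matching they were lost for pluripotency in anti-FoxA1 48 h (97.9) and anti-FLAG 48 h (98.98) and endoderm in anti-FoxA1 48 h (97.8), and by gene interval for the same, at 98.8, 98.8 and 98.7. With higher scores alone endoderm in anti-FoxA1 48 h was lost (97.8), and it was also lost by event number (94.8) and at equal size (94.3). The FoxA1 Hox result reversed by event number (17.9) and at equal size (28.1). The other changes were lost calls of feedback, Forkhead and Hox lists.

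No paired analysis was possible because the replicate numbers belong to libraries whose events stand in 1 combined list per factor, and the time courses have 1 library per point. Leaving out each replicate could not be run for the same reason. Motif alternatives were not run, as no sequence was in the reference used. Depth is unknown and limits every comparison of list lengths.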

Other observations

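The histone gene counts, and the tests of list size and of a transcribed unit for the miR-290 cluster, were chosen only after the results were seen.

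Histone genes of the large cluster on chromosome 13 drew events in some lists and not in others. Within 1 kb of the ends of its 54 protein-coding histone genes lay 39 events of the combined FoxA1 list. Anti-FoxA1 had 9 there at 24 h and 11 at 48 h, anti-FLAG had 3 and 1, FoxP3 had 2, FoxC1 had 1 and FoxL2 had 0. These genes are near copies of each other, how reads that match several were placed is not given in the sources used here, and the counts were not tested.

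Over the miR-290 cluster (chromosome 7, 3218626–3220841) and 2 kb to either side lay 13 FoxA1, 12 FoxC1 and 11 FoxP3 events, but 0 of FoxL2. List size alone predicts at least as many events in the anti-FoxA1 list at 24 h as in the combined FoxA1 list. The anti-FoxA1 list had 2 events there, 0.154 (exact binomial 95% interval 0.0169–0.680) of the combined FoxA1 count, where the ratio of the list lengths was 1.07. The interval treats events as independent, which combined FoxA1 events at a median gap of 359 bp may not be. List size is thus argued against only by the bare counts at 1 locus. Enrichment of a highly transcribed unit in every library was argued against by the 0 events of FoxL2, whose list is longer than those of FoxC1 and FoxP3. A broad signal split by the caller into evenly spaced events may still account for the pattern: events of different lists coincided within 50 bp in 50% of 36 events where rotated positions gave 38.2%, with a permutation p of 0.154, which the prediction written beforehand would have read as fitting, but which is left open here because the coincidence lay above the rotated mean. A difference between library batches was not tested, and no biological explanation was tested.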
